A study of Rattus norvegicus with 16 samples.

How the data were processed

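Liver RNA of adult rats aged 8 to 10 weeks was compared on 16 dual-channel oligonucleotide arrays from MWG, 8 of the Rat 5K kind and 8 of the Rat Liver kind. Per the labels' protocols, male rats received rat growth hormone (GH) by osmotic minipump at 2 µg per 100 g body weight per h for 7 days, and poly(A) RNA of single livers was labelled with Cy3-dUTP or Cy5-dUTP during reverse transcription. Each array held the cDNA of 1 untreated male beside that of 1 female or 1 GH-treated male, drawn at random from 4 animals per group. On each kind of array, 4 arrays formed the sex group and 4 the GH group. The labels state that the same hybridisations were run on both kinds with cDNA labelled in duplicate, so the kinds repeat the measurement technically and add no animals.

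The deposited values are log2 ratios of the 2 channels, which the authors normalized by lowess with f = 0.2 within each array, per the labels. The log base was checked on the values. Raised as powers of 2, 99.96% of the Rat 5K values and 99.88% of the Rat Liver values were whole thousandths, with a tolerance of 0.01 thousandths. Scanner, image software, background correction and spot filters are not given in the sources used here. Channel intensities were not used here, so dim spots could not be filtered and signal over background is unknown. The number of arrays limits the precision that can be stated. The Rat 5K arrays held 4614 to 5733 values each for 5760 spots, and the Rat Liver arrays 1060 to 1404 for 1440 spots.

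Of the Rat 5K spots, 15 had no value on any array and 259 held the same values as another spot on every array. The latter were taken as repeats without a check that both spots carried the same probe. Without these spots 5486 probes were left, of which 4953 had 1 gene symbol in the platform annotation, 7 had several and 526 had none. For the Rat Liver arrays, 32 spots had no value and 45 were repeats. Of the 1363 remaining probes, 1085 had 1 symbol, 3 had several and 275 had none. A RefSeq gene table held 4932 and 1077 of the single-symbol probes' genes under the same symbol and changed none. Probes of 1 gene were averaged per array, which gave 4375 genes on the Rat 5K and 1054 on the Rat Liver arrays. Probes without a single symbol were kept as features of their own and are not named. No genome was used, so no coordinates are given.

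The test, the samples in each fit, the rule for named genes, the rule for the direction of the ratios, 21 gene lists and most alternatives were chosen before the data were examined. Each kind of array was fitted apart with limma 3.58.1 in R 4.3.3, all 8 arrays in 1 fit, and limma's moderated test compared each group's mean log2 ratio with 0 and the 2 means with each other. The tests were two-sided, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. A feature needed a value on all 4 arrays of a group, or on both of the 2 arrays in the Rat 5K GH mean. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, for lists with at least 3 members measured on all 8 arrays. These can be fewer than the members counted, such as 12 of 18 male-biased genes for sex on the Rat Liver arrays and 12 of 14 female-biased genes for GH on the Rat 5K arrays. In the list of ribosomal proteins, the S6 kinase genes, whose symbols begin alike, were left out. Intervals of shares are exact binomial intervals at the 95% level and cover counting error only.

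Titles name the female or GH-treated animal first. Of the textbook sex-biased genes past the sex threshold, 14 of 15 on the Rat 5K and 14 of 14 on the Rat Liver arrays went against the reading of the values as first-named over second-named. By the rule fixed beforehand, the sign of every array was therefore turned. The values below are log2 of female over male and of GH-treated male over male. The textbook genes do not independently check this direction. Beyond that, 2 of the 4 Rat 5K GH arrays, replicates 3 and 4, are titled with the dyes in the other order, although the protocol text gives untreated males Cy5 throughout. Over all features they correlated with the other GH arrays at r = -0.19 to -0.09. This lay between the limits of the fixed rule, so these arrays were left out of the directed GH mean on the Rat 5K arrays, where n = 2. They stayed in the fit with a coefficient of their own, a step chosen after the correlations were seen, so that they add to the estimate of the spread. In a check chosen after the data were seen, arrays 3 and 4 as deposited correlated across genes with each Rat Liver GH array at r = 0.209 to 0.443 and 0.175 to 0.295. The dye-term values therefore read them as deposited.

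Named genes were, per kind of array and comparison, the 7 highest and 7 lowest mean log2 ratios among genes past the threshold with the same sign on all arrays of the mean. Up to 4 genes at each end were to be named for the difference between sex and GH. Every textbook sex-biased gene past a threshold was added, and the 4 members with the smallest adjusted p of each other list that passed camera. Genes outside this rule are described as chosen after their values were seen, and members of a list are given as examples of it.

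Same-numbered sex and GH arrays of the Rat Liver kind deviated together from their group means, with r = 0.33, 0.41, 0.43 and 0.38 for the 4 numbers, so the numbers were taken to pair these arrays. The labels give the numbers and do not say what they stand for. A fit with the number as a block was run for the difference between sex and GH. Both comparisons are against untreated males, so 50 simulated data sets without any effect, in which males carried 0.5 of the variance, gave the correlation that shared males alone produce.

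Alternatives were centring each array on its median, scaling arrays to equal spread, probes in place of genes, fits of only the arrays compared, a value on at least 3 of 4 arrays (counted over all 4 GH arrays on the Rat 5K kind), a robust variance estimate, array weights, a minimum absolute log2 ratio of 1, and each replicate left out. For the Rat 5K GH arrays they were a dye term, the other sign for the 2 arrays of other dye order, and a fit without them. A dye term for the remaining Rat 5K results, the 4 GH arrays averaged as deposited, a dye term with the sign of the 2 arrays turned, the blocked list tests, and an estimated correlation with the dye term or the block were added after the data were seen.

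The steps were tested on simulated data with 200 changed genes. At a log2 change of 1, the sex test recovered 94.0% of changed genes among 3696 Rat 5K features and 100% among 1261 Rat Liver features. The GH test recovered 82.1% among 4703 Rat 5K features and 100% among 984 Rat Liver features. The test of the difference recovered 70.1% among 3686 Rat 5K and 92.5% among 935 Rat Liver features. With the dye term on the Rat 5K arrays it was 76.1% for sex and 95.5% for GH, both among 3686 features. False calls made up 0 to 8.82% of all calls, the highest share with the replicate number as a block on the Rat 5K arrays. Dye effects were simulated only for the fits with the dye term. For the other fits, recovery and false calls therefore take no account of dye bias.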

Results

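Male rats release growth hormone in pulses and females more continuously, and the hormone's pattern is a known regulator of sex-biased liver enzymes. The arrays asked which liver transcripts depend on sex and which respond when males are given GH as a continuous infusion. Each of the 2 kinds of array gave 4 female to male ratios and 4 GH-treated male to male ratios from pairings of single animals. The labels put the same hybridisations on both kinds. The Rat 5K arrays gave 4614 to 5733 values each, and the Rat Liver arrays 1060 to 1404.

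Female liver held far less transcript than male liver of the estrogen sulfotransferase Sult1e1, the major urinary protein Mup5, the steroid hydroxylase Cyp2c11 and the carbonic anhydrase Car3. It held far more of the hydroxysteroid sulfotransferases Sult2a1 and Sult2a2 and of the steroid sulfate hydroxylase Cyp2c12. The signs follow the turned direction, which rests on these same textbook genes. The female to male log2 ratio of Sult1e1 was -4.21 ± 2.00 on the Rat Liver arrays (SD, n = 4, adjusted p = 0.00851), an 18.5-fold difference, and that of Cyp2c11 was -3.11 ± 1.84 (adjusted p = 0.00496). For Sult2a2 it was 3.05 ± 1.05 (adjusted p = 0.000532), an 8.30-fold difference, and for Cyp2c12 2.93 ± 1.73 (adjusted p = 0.00656), in which replicate 3 stood apart at 5.51.

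The other genes at the lower end on the Rat Liver arrays were Mup5 (-4.00 ± 2.56), Car3 (-2.87 ± 1.48), the hydroxyacid oxidase Hao2 (-2.67 ± 0.85), the prostaglandin D synthase Hpgds (-2.40 ± 0.85) and Hsd11b1 (-2.16 ± 0.45), which regenerates active glucocorticoid. At the upper end stood Sult2a1 (2.61 ± 0.87), the P450 genes Cyp2c7 (1.29 ± 0.49) and Cyp2e1 (1.28 ± 0.43), the cell adhesion gene Nptn (1.26 ± 0.31) and the glutathione transferase Gsta3 (1.17 ± 0.38). Their adjusted p values ran from 0.000376 to 0.00470, and each had the same sign on all 4 arrays. Of 1261 features tested, 33 were higher in females and 45 higher in males by limma's test. Without replicate 1 limma made 88 calls, of which more were female-higher (54) than male-higher (34). It made 31 calls with replicate 2 left out (14 and 17), 33 without replicate 4 (17 and 16) and 43 without replicate 3 (21 and 22), against 78 with all arrays.

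Cyp2c11 was the lowest named gene in females on the Rat 5K arrays, at -3.85 ± 1.95 (SD, n = 4, adjusted p = 0.0119), before Car3 at -3.77 ± 1.66 and Hao2 at -2.57 ± 0.52. The muscarinic receptor gene Chrm2 (-2.50 ± 0.47), the trypsin inhibitor Spink1 (-2.14 ± 1.24), Hsd11b1 (-2.07 ± 1.08) and Cyp3a2 (-1.86 ± 1.12) followed. Highest in females were the annexin Anxa4 (2.35 ± 0.66), Cyp2c12 (2.33 ± 1.02), the clock-controlled transcription factor Dbp (2.30 ± 0.86), Sult2a1 (2.27 ± 1.07, with replicate 1 apart at 3.88), the fatty acid carrier Cd36 (2.21 ± 1.52), the prolactin family gene Prl6a1 (2.17 ± 0.71) and the growth factor Bmp4 (2.07 ± 0.60). Adjusted p values of these 14 genes ran from 0.000752 to 0.0303, and each had the same sign on all 4 arrays. In all, 125 of 3696 features were female-higher and 73 male-higher. Anxa4, Prl6a1 and Bmp4 turned to -0.33, -0.38 and -0.53 when a dye term taken from the GH arrays of both dye orders was added. Anxa4 lay at -0.04 on the Rat Liver arrays (adjusted p = 0.954).

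Every sex array carried the male in the same dye, so the dye order and sex were separated only through the GH arrays of the Rat 5K kind. With that dye term, a choice made after the data were seen, 8 features were female-higher and 11 male-higher. These 19 included the male-higher Hao2 (-2.72), Chrm2 (-2.40) and Cyp4a2 (-1.25) and the female-higher Dbp (2.52), A1bg (1.89), Akr1c14 (1.29) and Fdps (1.16). The dye term widens the error of the sex ratio, and Cyp2c11 lost its call while keeping a ratio of -2.99 (adjusted p = 0.486). Over the 125 female-higher features the median ratio was 1.04 without the term and 0.291 with it, and 41 changed sign. Over the 73 male-higher features it was -0.763 and -0.564, and 3 changed sign. Left-out replicates also moved the count of 198, to 38 without replicate 1, 15 without replicate 2, and 128 without replicate 3.

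Genes known from textbooks as male-biased in rat liver were lower in females as a group, though the textbook genes, male- and female-biased, set the sign of every array. Among 18 measured members, 9 fell and none rose on the Rat Liver arrays, and adjusted over the list alone 10 fell and 1 rose. Over the 12 members with a value on all 8 arrays, the camera adjusted p was 8.37e-11, against adjusted p = 0.156 with an estimated correlation. Examples beyond those above were Cyp2c22 (-1.51), Cyp3a18 (-1.35), Sult1c3 (-1.07) and the fatty acid hydroxylase Cyp4a2 (-1.05). Of 18 on the Rat 5K arrays, 8 fell and 1 rose, and adjusted over the list alone 9 fell and 2 rose (camera adjusted p = 0.000354, adjusted p = 0.461 with an estimated correlation). Cyp3a18 (-1.67), Cyp2c22 (-1.77), Hsd3b5 (-1.52) and Cyp4a2 (-1.30) were among them, and the member that rose was the steroid reductase Akr1c14 (0.98 ± 0.28, adjusted p = 0.00284).

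Of the textbook female-biased genes, 6 of 12 rose on the Rat 5K arrays, the same number adjusted over the list alone, and none fell (camera adjusted p = 0.00383, adjusted p = 0.565 with an estimated correlation). These were Cyp2c12, Sult2a1, A1bg (1.52 ± 0.51), the alcohol dehydrogenase Adh1c (1.30 ± 0.33), Cyp2c7 (1.12 ± 0.67) and the prolactin receptor Prlr (0.83 ± 0.59). The probes of A1bg disagreed, at -0.05 and 3.10, and the 5 probes of Prlr ran from 0.15 to 2.24. Of 9 on the Rat Liver arrays 5 rose, including Adh1c (0.99 ± 0.71), and adjusted over the list alone 5 rose and 2 fell. Camera, over 5 members, did not pass there (adjusted p = 0.173).

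Enzymes of fatty acid and cholesterol synthesis were also female-higher as a group on both kinds of array. Of 22 on the Rat 5K arrays 4 rose and none fell, or 10 adjusted over the list alone (median 0.30, camera adjusted p = 0.000315, adjusted p = 0.340 with an estimated correlation). They were Fdps, which makes farnesyl diphosphate (1.00 ± 0.22, adjusted p = 0.00162), the sterol enzymes Sc5d (0.84 ± 0.35) and Cyp51 (0.75 ± 0.28), and the lipogenic regulator Thrsp (0.92 ± 0.68). Of 14 on the Rat Liver arrays 1 rose, Fdps at 1.02 ± 0.33 (adjusted p = 0.00222), or 5 adjusted over the list alone (median 0.55, camera over 11 members adjusted p = 0.00543, adjusted p = 0.506 with an estimated correlation).

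Other lists moved in both directions or did not pass camera for sex without the dye term. On the Rat 5K arrays 5 of 32 cytochrome P450 genes rose and 5 fell, while adjusted over the list alone 6 rose and 6 fell (camera adjusted p = 0.952, with median and mean below 0 and the test's direction up). Of 24 on the Rat Liver arrays 4 rose and 5 fell, and adjusted over the list alone 5 and 6 (camera adjusted p = 0.657, with the median above 0 and mean and test below). Conjugating enzymes likewise split, with 5 of 21 rising and 3 falling on the Rat Liver arrays, where Gsta3 rose and Sult1e1 fell, and adjusted over the list alone 5 rose and 4 fell. On the Rat 5K arrays 4 of 26 rose and 1 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.377). Among plasma proteins 5 of 40 fell on the Rat 5K arrays, including apolipoprotein Apoa1 (-0.82) and the fibrinogen chain Fga (-0.73), and none rose. Adjusted over the list alone, 7 fell and 1 rose, and the list's median of 0.01 differed in sign from its mean and test. No ribosomal protein gene of 69 passed on the Rat 5K arrays, over all genes or adjusted over the list alone, but with the dye term the list passed upward (camera adjusted p = 1.53e-10, and 0.458 with an estimated correlation). On the Rat Liver arrays 1 of 51 fell, Rpl30 (-0.66, adjusted p = 0.0416), and none adjusted over the list alone. Among markers of other cell types, the macrophage marker Cd14 (-0.86, adjusted p = 0.0282) and the collagen gene Col3a1 (-0.71, adjusted p = 0.0182) fell on the Rat 5K arrays, and no lymphocyte, endothelial, bile duct or red cell marker passed.

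**Figure D1:**
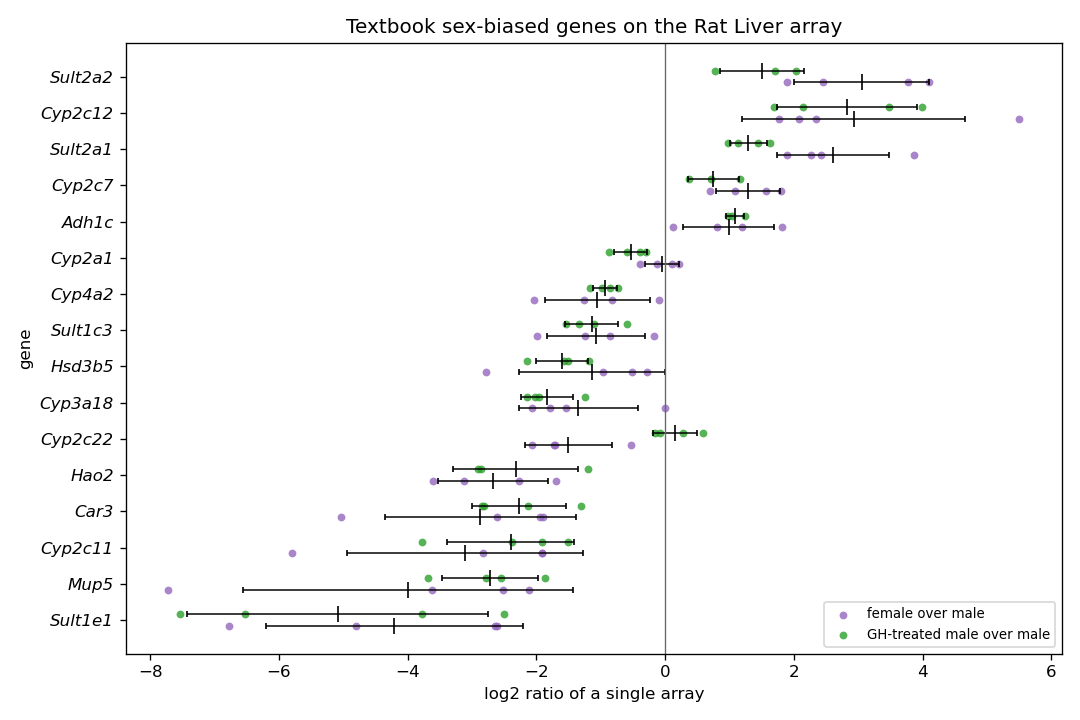
Log2 ratios of single Rat Liver arrays (points) for textbook sex-biased genes past a threshold in either comparison, with mean and SD as bars, female over male in purple and GH-treated male over male in green, with 4 arrays each or fewer where a value was missing. Cyp2c22 lay at -1.51 for sex and 0.16 for GH, while most other genes lay on the same side of 0 in both.

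Males given continuous GH held less than untreated males of transcripts known as male-biased, among them Sult1e1, Cyp2c11 and Car3, and more of Cyp2c12. The GH-treated male to male log2 ratio of Sult1e1 on the Rat Liver arrays was -5.09 ± 2.34 (SD, n = 4, adjusted p = 0.00459), a 34.0-fold difference, and that of Cyp2c11 was -2.40 ± 0.99 (adjusted p = 0.0235). Cyp2c12 rose by 2.83 ± 1.08 (adjusted p = 0.00976), a 7.10-fold difference. The gluconeogenic enzyme gene Tat rose by 1.33 ± 0.72, the sterol regulator Insig1 by 1.43 ± 0.81 and Sult2a1 by 1.30 ± 0.29.

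Mup5 (-2.72 ± 0.75), Car3 (-2.27 ± 0.73), Hpgds (-2.20 ± 0.58), Cyp3a18 (-1.84 ± 0.40) and Hsd3b5 (-1.60 ± 0.41) completed the lower end on the Rat Liver arrays. The arachidonate epoxygenase Cyp2c23 (1.29 ± 0.67), the sialyltransferase St6gal1 (0.96 ± 0.45) and the plasma protein gene Itih4 (0.91 ± 0.53) completed the upper end. Adjusted p values of these 14 genes ran from 0.00367 to 0.0389, and each had the same sign on all 4 arrays. Of 984 features tested, 22 rose and 31 fell by limma's test. Leaving out replicates 1, 2, 3 and 4 in turn gave 33, 14, 30 and 34 calls, against 53 with all arrays. Replicate 1 lacked 380 of 1440 values, which keeps the number of features tested below that for sex.

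Where the mean held 2 arrays, on the Rat 5K kind, Hsd11b1 was lowest at -3.57 ± 1.07 (SD, n = 2, adjusted p = 0.0240), before the P450 gene Cyp2c13 at -2.89 ± 0.48, Chrm2 at -2.68 ± 0.17 and Hao2 at -2.26 ± 0.79. The splicing factor Srsf5 (-2.16 ± 0.92), Tfpt (-2.14 ± 0.31), Cyp3a18 (-2.07 ± 0.33) and the textbook gene Hsd3b5 (-2.05 ± 0.11) followed. All of them were also negative on the 2 arrays of the other dye order, where Chrm2 lay at -2.48 and Cyp2c13 at -3.60. Srsf5 lay at -0.12 on the Rat Liver arrays (adjusted p = 0.764). The 7 highest were Npy4r (2.53 ± 0.40), Bmp4 (2.14 ± 0.12), Hsd3b2 (2.11 ± 0.41), Prl6a1 (2.09 ± 0.04), the platelet glycoprotein Gp5 (2.04 ± 0.50), the laminin gene Lama5 (1.97 ± 0.17) and Anxa4 (1.95 ± 0.35). Every one of these 7 was negative on the arrays of the other dye order, at -3.42 for Anxa4 to -1.89 for Npy4r.

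In all, 17 of 4703 features rose and 17 fell on the Rat 5K arrays, and 516 had an unadjusted p under 0.05. Without replicate 1 or without replicate 2, 1 array was left in the mean, taken to vary like the other groups, and limma made 0 calls, with 504 and 170 features at an unadjusted p under 0.05. With the dye term, which uses all 4 GH arrays, 26 features rose and 40 fell among 3686. Of these 66, Car3 (-3.17), Cyp3a2 (-2.77), Hsd11b1 (-2.70), Chrm2 (-2.58) and Hao2 (-2.41) were lowest and Cyp2c12 (2.42), A1bg (1.72), the desaturase Scd (1.62), Insig1 (1.46) and Kng2l1 (1.31) highest. The genes named for the dye term were chosen after their values were seen.

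**Figure D2:**
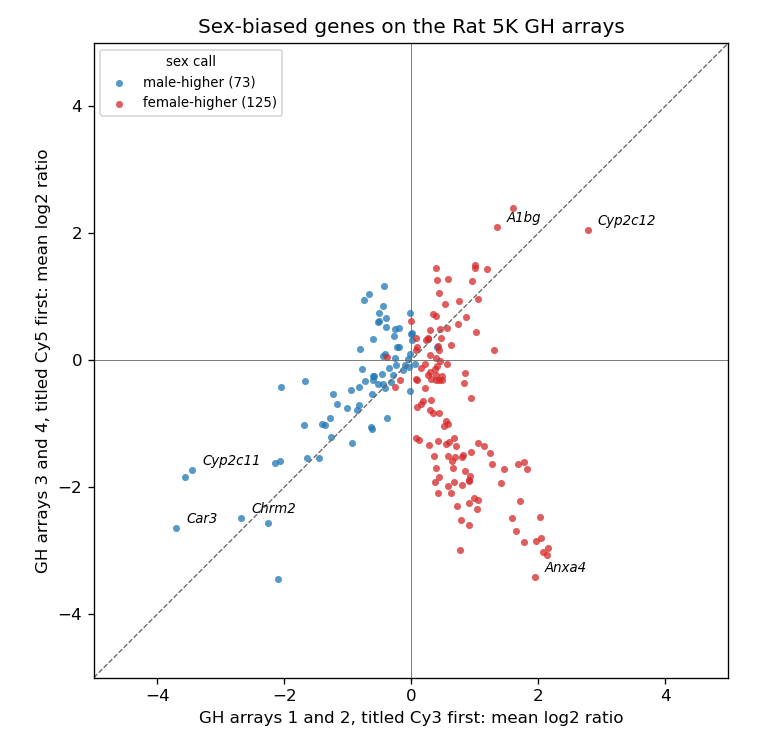
Features past the sex threshold on the Rat 5K arrays, with the mean log2 ratio of GH arrays 1 and 2 on the x axis and of GH arrays 3 and 4, titled with the dyes in the other order, on the y axis; points are features, male-higher (73) in blue and female-higher (125) in red, and the dashed line marks equal values. The median on the y axis was -0.253 for the male-higher and -0.732 for the female-higher features, with Anxa4 at -3.42.

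The textbook male-biased list moved down with GH on both kinds of array. Of 12 on the Rat Liver arrays 8 fell, or 9 adjusted over the list alone, and none rose (median -1.37, camera adjusted p = 9.40e-08, adjusted p = 0.324 with an estimated correlation). Sult1c3 (-1.14 ± 0.41) and Cyp4a2 (-0.93 ± 0.19) were among them. Of 19 on the Rat 5K arrays 4 fell, or 10 adjusted over the list alone, and none rose (median -0.40, camera adjusted p = 2.09e-07, adjusted p = 0.333 with an estimated correlation). Of the textbook female-biased genes on the Rat Liver arrays, Cyp2c12 and Sult2a1 rose and Cyp2a1 fell by 0.54 (adjusted p = 0.0479) among 6, and adjusted over the list alone 3 rose and 1 fell. Camera gave adjusted p = 0.413 there. None of 14 passed on the Rat 5K arrays, and 3 rose adjusted over the list alone (camera adjusted p = 0.109, and with the dye term 0.00277 upward, or 0.525 with an estimated correlation).

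Lipid and cholesterol synthesis moved up with GH on the Rat 5K arrays (median 0.26, camera adjusted p = 0.00936, adjusted p = 0.333 with an estimated correlation), although none of 23 members passed alone and 1, Scd, did so adjusted over the list alone. Insig1 rose among 12 on the Rat Liver arrays, the same adjusted over the list alone, and camera gave adjusted p = 0.0544. Plasma proteins moved up on the Rat 5K arrays (median 0.18, camera adjusted p = 0.0237, adjusted p = 0.585 with an estimated correlation), and did not pass with the dye term (adjusted p = 0.344). None of 40 passed alone, and adjusted over the list alone 5 rose and 2 fell. The complement gene C3 (0.90) and Itih4 rose on the Rat Liver arrays while the thyroid hormone carrier Ttr (-0.80) and Fga (-0.59) fell, the same 4 of 33 adjusted over the list alone (camera adjusted p = 0.413).

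Ribosomal protein genes lay lower with GH on the Rat 5K arrays (median -0.28 over 70 genes, camera adjusted p = 2.67e-11, adjusted p = 0.581 with an estimated correlation). None passed alone, and 2 did adjusted over the list alone. Their median on the Rat Liver arrays was -0.04 over 43 genes and camera gave adjusted p = 0.413, with Rpl5 (-0.70) and Rpl30 (-0.66) past the threshold and 3 adjusted over the list alone. Red cell markers also lay lower on the Rat 5K arrays (median -0.51 over 4 genes, camera adjusted p = 0.0134, adjusted p = 0.333 with an estimated correlation), and none of the 4 passed alone against 2 adjusted over the list alone. The list did not pass with the dye term (adjusted p = 0.226). The haem enzyme gene Alas2 had -0.93 and the globin gene Hba-a1 -0.74. No marker of macrophages, lymphocytes, stellate cells, endothelium or bile ducts that was measured passed for GH over all genes on either kind of array.

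Whether sex and GH acted differently on a gene was tested as the female to male minus the GH-treated male to male ratio. The P450 gene Cyp2c22 had the lowest adjusted p on the Rat Liver arrays, at -1.51 for sex and 0.16 for GH, a difference of -1.66 (adjusted p = 0.142). Limma called 0 of 935 features on the Rat Liver arrays, with 34 at an unadjusted p under 0.05, and 0 of 3686 on the Rat 5K arrays, with 185. With the replicate number as a block on the Rat Liver arrays, where the numbers paired the arrays, 2 genes passed. They were Cyp2c22 (-1.66 ± 0.17 SE, adjusted p = 0.0113) and the sterol synthesis enzyme Sqle (1.00 ± 0.13 SE, adjusted p = 0.0352, against 0.884 without the block), at 0.69 for sex and -0.31 for GH. Both were named after their values were seen. Without the block, 1 feature passed when replicate 4 was left out. As groups on the Rat 5K arrays, ribosomal proteins lay higher for sex than for GH (median difference 0.36, camera adjusted p = 2.81e-18, adjusted p = 0.390 with an estimated correlation). Plasma proteins lay lower (median -0.29, camera adjusted p = 0.000447, adjusted p = 0.390 with an estimated correlation). With the replicate number as a block on the Rat 5K arrays, limma called 0 features, with 495 at an unadjusted p under 0.05. Ribosomal proteins passed with that block (camera adjusted p = 8.59e-05), the textbook female-biased list passed upward (adjusted p = 0.0373), and plasma proteins did not (adjusted p = 0.0904). With an estimated correlation as well, the first 2 gave adjusted p = 0.576 and 0.643 and no list passed. Adjusted over the list alone, no member of either list passed, and no list passed on the Rat Liver arrays.

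Many sex calls also passed for GH. Of the 57 Rat Liver sex calls tested in both comparisons, 28 also passed for GH in the same direction (49.1%, exact binomial 95% interval 35.6 to 62.7%) and 0 in the opposite one. Of 23 female-higher features 9 were higher with GH, Cyp2c12, Sult2a1 and Gsta3 among them, and of 34 male-higher features 19 were lower, including Sult1e1, Cyp2c11, Car3 and Hpgds. Independent lists of these sizes would share 0.517 raised and 1.09 lowered features. Cyp2c22, Dio1 and Mug1 passed for sex with GH ratios of 0.16, -0.22 and -0.07. These latter genes were chosen after their values were seen, and for none of them did the difference pass without the block. The share was 25.6% without replicate 1 and 17.4% without replicate 2.

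Of 198 Rat 5K sex calls, 26 passed for GH in the same direction (13.1%, interval 8.76 to 18.6%) and 0 in the opposite one, against 0.475 raised and 0.317 lowered features for independent lists. The 14 shared female-higher features included Anxa4, Bmp4 and Prl6a1, which were negative on the GH arrays of the other dye order. With the dye term for both it was 14 of 19 (73.7%, interval 48.8 to 90.9%), with Hao2, Chrm2, A1bg and Fdps among the 14. Independent lists would share 0.0564 raised and 0.119 lowered features. Both ratios then draw on the same GH arrays, and unchanged groups were not simulated for that fit. The 14 of 19 reads GH arrays 3 and 4 as deposited, and with their sign turned it was 41 of 72 (56.9%, interval 44.7 to 68.6%). The GH ratio of that turned fit equals the dye coefficient of the fit as deposited. If the deposited signs hold, the 41 of 72 is therefore overlap with dye bias and no estimate of the overlap with GH. Leaving out replicate 1 or replicate 2 left 1 array in the GH mean, so the share says nothing of the overlap there. Without replicates 3 and 4 in turn the share was 25% and 8.36%.

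Across features, sex and GH ratios correlated at r = 0.803 (rho = 0.616) on the Rat Liver and r = 0.677 (rho = 0.517) on the Rat 5K arrays, and genes are not independent replicates. On the latter the dye term gave r = 0.462 (rho = 0.186) and a covariance of 0.0439. Simulated unchanged groups that shared their males, fitted without the dye term, gave r = 0.509 and 0.354 and 0 shared calls. The covariance was 0.131 against 0.0150 simulated on the Rat Liver arrays and 0.106 against 0.0132 on the Rat 5K arrays. Between pairs of arrays with no replicate number in common r was 0.490 and 0.522 on the Rat Liver arrays. For the Rat 5K kind it was 0.552 for sex arrays 3 and 4 with GH arrays 1 and 2, and -0.426 for sex arrays 1 and 2 with GH arrays 3 and 4, which have the other dye order.

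**Figure D3:**
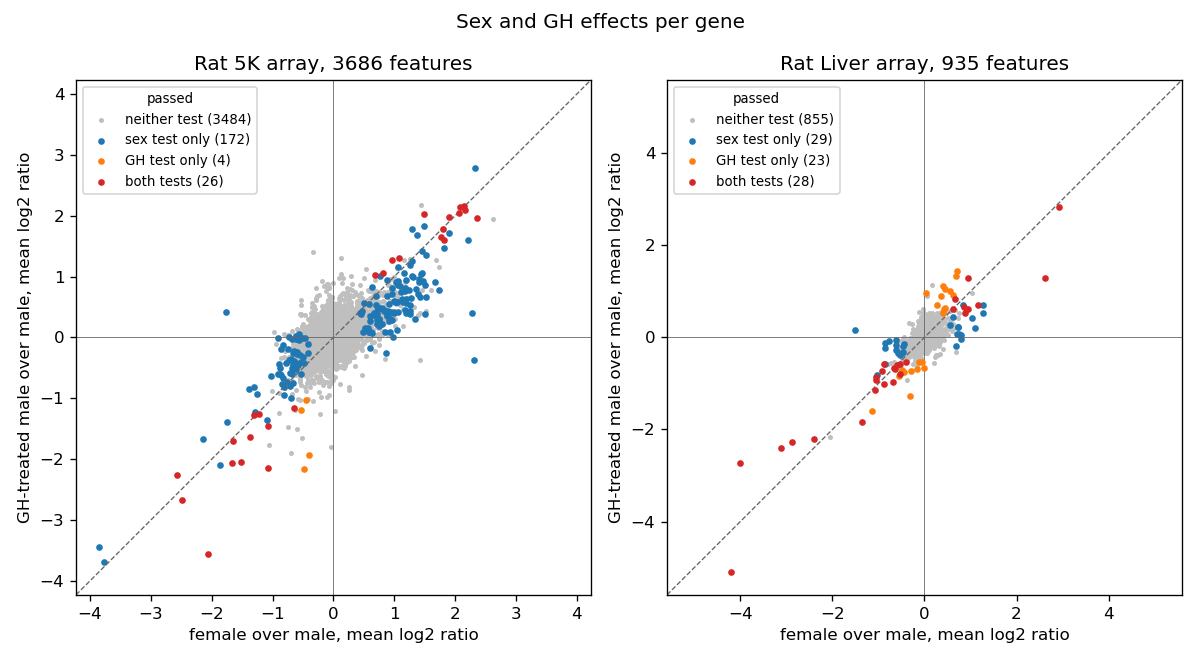
Mean log2 ratio of female over male (x axis) against GH-treated male over male (y axis) for the 3686 Rat 5K and 935 Rat Liver features tested in both comparisons, with colours for the tests passed; the dashed line marks equal ratios. Both tests were passed by 28 Rat Liver and 26 Rat 5K features, all with the same sign.

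Genes on both kinds of array were measured from the same pairings, and most but not all had like ratios. For sex, 935 genes correlated at r = 0.745 (rho = 0.575), and 26 genes were called on both, all with the same sign, against 3.47 for independent lists of 56 and 58 calls. Cyp2c11, Car3, Hao2, Hsd11b1, Cyp2c12, Sult2a1 and Fdps were among them. Of the 88 genes called on either kind, 83 had the same sign on both and 5 the opposite one, and 4 lay over 1 log2 apart. These 4 were Anxa4 (2.35 on the Rat 5K and -0.04 on the Rat Liver arrays), Hpgds (-0.35 and -2.40), Suclg1 (-0.12 and -1.29) and Nptn (0.25 and 1.26). The dye term on the Rat 5K arrays left 7 sex calls shared, all with the same sign. For GH, 757 genes correlated at r = 0.683 (rho = 0.507), and 4 genes, Acsl5, Cyp3a18, Enpp2 and Hsd3b5, were called on both. Of 43 genes called on either kind for GH, 39 had the same sign, and Srsf5 (-2.16 and -0.12), Hpgds (-0.48 and -2.20), Car3 (-3.70 and -2.27) and Cyp2c11 (-3.45 and -2.40) lay over 1 apart. With the dye term on the Rat 5K arrays 17 GH calls were shared, again all with the same sign, against 1.61 for independent lists. That fit reads GH arrays 3 and 4 as deposited because of their correlation with the Rat Liver GH arrays. The 17 are therefore partly built in.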

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

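The tests of dye bias, whole-array offset, shared males, dye order, the deposited sign of 2 arrays and splits with a block were chosen only after the results were seen, while the tests of sign patterns and of other splits were not.

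More features were female-higher (125) than male-higher (73) on the Rat 5K arrays. A remaining offset of whole arrays was argued against, since the female-higher share was 67.7% with each array centred on its median and 63.1% before. The dye coefficient, taken from the GH arrays of both dye orders alone, had a median of 0.589 over the female-higher features (quartiles 0.0943 to 1.30) and -0.181 over the male-higher ones, so dye bias of single probes may account for part of the excess, with GH arrays 3 and 4 read as deposited. It is less of a candidate for the 30 female-higher genes also on the Rat Liver arrays, where 29 had the same sign (median 0.628) in the same dye order, as their dye coefficient had a median of 0.0546, against 0.938 for the other 95. The 8 sign patterns of the 4 sex ratios are too few for a share under 0.05 (1, the real one with 198 features, gave as many, and the highest other 0), and a difference between the sexes stays open, untested on arrays with the male in the other dye.

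Sex and GH ratios correlated across genes on both kinds of array. Males shared by same-numbered arrays are argued against as the whole cause, since Rat Liver arrays with no number in common still gave r = 0.490 and 0.522, against 0.762 and 0.712 with the same numbers. The shared dye order stays open. Features were ranked on 2 Rat 5K sex arrays, and signs were read from 1 GH array of each dye order with no number in common. Of the 73 at the male-higher end, 72.6, 65.8, 72.6 and 52.1% had the same sign in the 4 arrangements. Over all features ranked it was 50.4, 44.7, 48.3 and 38.4%, below the male-higher end each time. Of the 125 at the female-higher end it was 51.2, 32, 42.4 and 30.4%, near or below the share of all features. With GH arrays 3 and 4 turned the ends gave 71.2 to 79.5% and 76.8 to 88.8%. With the dye term the Rat 5K correlation was r = 0.462, against 0.677, but unchanged groups were not simulated for that fit. A first test took the median of the male-higher features on arrays 3 and 4, which was -0.253 (quartiles -0.91 and 0.21). Its written bound, a median below -0.25, was just met and counted against the dye order. The upper quartile was also required to lie below -0.25, which that bound did not ask, so the test was read as deciding nothing. A response to GH, which the design names, stays open as well and was not tested apart from the dye order on the Rat Liver arrays. Of 39 Rat Liver GH calls, 34 and 31 kept their sign on Rat 5K GH arrays 3 and 4, of the other dye order. These same values served to read the sign of arrays 3 and 4, so they cannot also part GH from the dye order.

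For the 78 sex calls and the 53 GH calls on the Rat Liver arrays, the 8 sign patterns of the 4 ratios are too few for a share under 0.05; in each case 1 pattern, the real one, gave as many features, and the highest other gave 0. The difference between sex and GH on these arrays gave 0 features by limma, with 34 at an unadjusted p under 0.05. With a real count of 0, all 35 splits of the 8 arrays give as many whatever the data (highest other 1), so they decide nothing. With the replicate number as a block it gave 2 genes; the 8 splits that part all pairs are too few for a share under 0.05, and 1 of them, the real one, gave as many, the highest other 0.

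Dixon's test set single arrays apart in some groups of 4. Chance alone does so in about 1 in 20 groups, or 3.95 of the 79 tested. The female to male ratio of Sult2a1 was 3.88 on Rat 5K replicate 1 and 1.59 to 1.87 on the others. That of Cyp2c12 was 5.51 on Rat Liver replicate 3 and 1.78 to 2.35 on the others. The same Rat Liver sex replicate 3 lacked 101 values, against 36 to 41 on the others, and its log2 ratios had an SD of 0.711, against 0.441 to 0.486. Rat Liver GH replicate 1 lacked 380 values, against 36 to 43, and 95.6% of the spots of 1 print block had none.

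The 2 Rat 5K GH arrays of the other dye order, outside the directed mean, held 261 features past the threshold as a pair, 97 higher and 164 lower of 4871. Of these 80 were also sex calls, 26 with the same sign and 54 with the opposite one as deposited, and 54 and 26 if the arrays were turned. A deposit of these arrays with the other sign is argued against, since 34 of the 39 Rat Liver GH calls measured on both kinds had the same sign on array 3 and 31 on array 4 (79.5%, exact binomial interval 63.5 to 90.7%). This takes the Rat Liver GH calls as responses to GH and not as dye bias.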

How the results depend on the processing

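The dye term for sex, overlap, agreement and lists, the average of all 4 Rat 5K GH arrays as deposited, the dye term with GH arrays 3 and 4 turned, the blocked list tests, and an estimated correlation with the dye term or the block were chosen after seeing the data. The cause was not tested for any of the values here unless fewer arrays or a stricter threshold are the alternative itself. Centring, probes in place of genes, at least 3 of 4 values and a robust variance kept the counts for sex and GH within 1.5 times of 198, 34, 78 and 53. Signal over background is unknown here and limits what can be said of dim spots.

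The 198 sex calls on the Rat 5K arrays became 362 (209 higher, 153 lower) with scaled arrays, 56 with only the arrays of the comparison, 91 (68 higher, 23 lower) with an absolute log2 of at least 1, 19 with the dye term, 72 with it and arrays 3 and 4 turned, and 15 to 275 with a replicate left out. These sex arrays differed in spread, with SDs of the log2 ratios of 0.724, 0.550, 0.528 and 0.309 for replicates 1 to 4. In the same order they lacked 1146, 610, 440 and 46 values. The 34 GH calls became 128 with scaled arrays, 68 with only the arrays of the comparison, 193 with array weights and 20 without the 2 arrays of other dye order. They became 66 with the dye term, 53 with it and those 2 arrays turned, and 39 and 25 without replicates 3 and 4 in turn. The 53 are the calls of the dye coefficient in the fit as deposited. With the sign of those 2 arrays turned there were 48 (40 higher, 8 lower), and with all 4 as deposited 41 (16 higher, 25 lower). The 78 sex calls on the Rat Liver arrays became 49 with only the arrays of the comparison, 26 with an absolute log2 of at least 1, and 31 to 88 with a replicate left out, and the 53 GH calls became 18 with an absolute log2 of at least 1 and 14 to 34 with a replicate left out.

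The difference between sex and GH stayed at 0 calls on the Rat 5K arrays in every fit tried, with 185 features at an unadjusted p under 0.05 by limma. On the Rat Liver arrays it was 1 at probe level, 0 to 1 with a replicate left out and 2 with the replicate number as a block. On the Rat 5K arrays GH deviations from a mean of 2 mirror each other, so the same check (r = 0.04, 0.23, -0.16 and 0.35 for the 4 numbers) decides little there. The replicate block gave 0 calls, with 495 features at an unadjusted p under 0.05. The dye term leaves the test of this difference unchanged, with or without the block, so its 0 calls are no further check. The block changed no other call of the difference among genes; of the lists on the Rat 5K arrays 2 passed with it, ribosomal proteins and the textbook female-biased genes, and plasma proteins did not. With an estimated correlation as well, 0 passed.

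The share of sex calls shared with GH on the Rat 5K arrays, 13.1%, was 18.8% with scaled arrays (68 in the same and 1 in the opposite direction), 42.9% with array weights and 24.2% with an absolute log2 of at least 1. With the dye term it was 73.7%. It was 56.9% with arrays 3 and 4 turned as well, where the GH ratio equals the dye coefficient of the fit as deposited. Without replicates 3 and 4 in turn the share was 25% and 8.36%. It was 5.24% for sex arrays 1 and 2 with GH arrays 3 and 4 (13 in the same and 63 in the opposite direction). The reverse halving of the Rat 5K arrays gave no value, as no sex call was made. On the Rat Liver arrays the share of 49.1% became 22.6% for sex arrays 3 and 4 with GH arrays 1 and 2 and 17.4 to 50% with a replicate left out. Agreement of both kinds for sex, r = 0.745, was 0.709 with the dye term, while calls shared by both kinds went from 26 to 7.

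With an estimated correlation in camera 0 lists passed, in place of 3 for sex, 5 for GH and 2 for their difference on the Rat 5K arrays, and of 2 for sex and 1 for GH on the Rat Liver arrays. With the dye term 8 lists passed for sex on the Rat 5K arrays, as ribosomal proteins (up, 1.53e-10), conjugation (up), plasma proteins (down, 0.0152), and glucose and amino acid metabolism and heat shock (up, both 0.0436) joined the 3. For GH 4 passed with it, the textbook female-biased list gained (adjusted p = 0.00277) and plasma proteins (0.344) and red cell markers (0.226) lost. An estimated correlation beside the dye term left 0 lists for sex or GH, and also 0 for their difference, whose test the dye term leaves unchanged.

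Among named genes, the dye term turned the Rat 5K sex ratio of Bmp4 to -0.53, Prl6a1 to -0.38 and Anxa4 to -0.33, and the GH ratio of Anxa4 to -0.73, Lama5 to -0.44, Gp5 to -0.38, Prl6a1 to -0.47 and Bmp4 to -0.46. The average of all 4 GH arrays as deposited gave these same 5 GH values and -0.049 for Hsd3b2. Turning the sign of the 2 arrays of other dye order took Cyp2c13 to 0.36 and Hao2 to 0.15, and with the dye term also it took Hao2 to 0.15 for GH and, for sex, Chrm2 to 0.082, Hsd11b1 to 0.63, Cyp3a2 to 0.90, Cyp3a18 to 0.15, A1bg to -0.20 and Cyp2c12 to -0.087. No other named gene changed sign under the alternatives in which it was followed. Named genes were not followed with probes in place of genes. The dye term covered 12 of the 15 named Rat 5K GH genes, without Cyp2c13, Hsd3b2 and Npy4r.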

Other observations

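The test of the dye coefficient of the clock gene Dbp was chosen only after the result was seen, and the clock test was not. The genes of the next paragraph were chosen after their values were seen.

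Some genes that passed for GH when arrays of both dye orders were used belong to lipid metabolism and others do not. Picked in this way they test no theme. With the dye term 4 gene lists passed camera for GH, and 0 with an estimated correlation (smallest adjusted p = 0.171). With the dye term on the Rat 5K arrays the acyl-CoA synthetases Acsl4 (1.26) and Acsl5 (1.01), the desaturase Scd (1.62), the kininogen Kng2l1 (1.31) and the alcohol dehydrogenase Adh1c (1.23) rose, and the autotaxin gene Enpp2 (-1.50) and the cobalamin carrier Tcn2 (-1.24) fell, by limma's test at an adjusted p under 0.05. Of these, Acsl5, Enpp2 and Tcn2 also passed without the dye term. Acsl5 also rose (0.67, adjusted p = 0.0479) and Enpp2 also fell (adjusted p = 0.00456) on the Rat Liver arrays, which repeat the same pairings, while Tcn2 did not pass there (-0.74, adjusted p = 0.162). Scd had a female to male ratio of -0.34 (adjusted p = 0.343), and its difference between sex and GH did not pass (-1.74, adjusted p = 0.677).

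Dbp, a clock-controlled transcription factor, was female-higher on the Rat 5K arrays at 2.30 ± 0.86 (SD, n = 4, adjusted p = 0.00315), with a GH ratio of -0.38, though the difference between sex and GH did not pass (2.68, adjusted p = 0.677). Dye bias of its probe is argued against, as its dye coefficient was -0.22. Livers collected at different clock times stay open: 11 measured clock output genes of its phase had a median female to male ratio of 0.159 (quartiles 0.0492 to 0.368), with Por at 1.20 past the threshold, while Bmal1, of the opposite phase, lay at -0.73 (adjusted p = 0.0246) and Clock at -0.09. By the bound set beforehand, a median below 0.25, the value of 0.159 counted against different clock times. A condition that the upper quartile lie below 0.25 as well was added after the median was seen, and it was not met. It was added because members reached from -0.10 to 1.20, and a median over such a spread decides little. A sex difference in Dbp may be present as well and was not tested apart from collection time.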
